A study of Drosophila melanogaster with 6 samples.

How the data were processed

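Small RNAs of 18 to 30 nt had been gel-purified after removal of 2S rRNA, ligated to adapters, amplified and sequenced on an Illumina GAIIX, per the labels' protocols, from flies reared at 24 °C. There were 6 libraries, 1 for each sex of larval salivary glands, adult heads and adult bodies without the head. The deposited files hold raw read counts, 1 count for each distinct read sequence of 16 to 36 nt, with no scaling, no miRNA names and no genome positions. The builds dm3 and BDGP5 were used per the submitters' processing notes. The aligner, the adapter trimming and any filter are not given in the sources used here.

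Reads were assigned to miRNAs by sequence. No miRNA sequence reference was at hand, so 157 known mature sequences were written from general knowledge, a few abundant reads having been seen before that list was written. A read of 18 to 30 nt counted for a miRNA when it matched it without a mismatch over at least 16 nt, started within 3 nt of its 5' end and ran at most 3 nt past its 3' end, where the added bases were not compared. Sequences with 10 or more reads over the 6 libraries were kept, 143 of 157, giving 133 miRNAs with the arms of a hairpin summed. Of the 143, 136 had reads of the exact full sequence and 132 had their commonest 5' end where it was searched. A miRNA missing from the list was not counted, so unmatched reads say nothing of absence. Loci with the same mature sequence were merged (mir-2a, mir-2b, mir-13b, mir-281 and mir-983), and the 5p arm shared by mir-276a and mir-276b was left out. The planned unit was the whole hairpin, and it was replaced by the mature arms for want of hairpin sequences. Chromosomes and coordinates came from the dm6 (BDGP6) annotation by gene symbol. No position was converted from the older builds. mir-13b, with loci on 3R and X, and mir-997, absent from the annotation, were left out of the X comparison. Fragments of rRNA and tRNA were counted by matches of 16 nt to sequences written after the most abundant reads had been seen.

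Counts were scaled with TMM factors over the miRNAs of all 6 libraries (edgeR 4.0.16, R 4.3.3). The factors were 1.03 and 0.719 for the male and female gland, 1.19 and 1.40 for the heads, and 1.01 and 0.805 for the bodies. Within a tissue the sexes were compared by the ratio of CPM with 0.5 reads added to each library and a Clopper-Pearson 95% interval. A miRNA passed when it had 100 or more reads in at least 1 of the 2 libraries, was at least 2-fold apart and had an interval excluding 1. A ratio against 0 reads was given as a bound against a floor of 3 counts, per library, or over both libraries of a tissue in the tissue comparisons. The sex difference common to the tissues and the 3 tissue comparisons were tested with edgeR's quasi-likelihood F test on tissue and sex over 125 miRNAs with 50 or more reads in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual degrees of freedom were 2, and a sex difference particular to a tissue counts as spread in these tests. The values given as SE were calculated back, as the absolute log2 value over the square root of F. They are approximate, above all where a group has few or no reads. DESeq2 1.42.0 was the other tool, and lists were tested with camera (limma 3.58.1), with its preset correlation and with an estimated correlation.

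Lists of miRNAs were the let-7 Complex, testis clusters, ovary, the mir-310 cluster, the early embryo mir-309 cluster, neuronal and sensory, muscle, growth and cell death, metabolism with gut and fat body, the mir-9b cluster, Hox loci and mirtrons. Of the testis list 19 miRNAs had reads, of the mir-309 list 4 and of the mirtrons 13. The percentile of a list's median was taken among 10000 random sets of its size matched on mean expression in 5 bins, as a description of the libraries. X-linked and autosomal miRNAs were compared by the difference of their median log2 ratios, with 500 resamplings of the counts for the counting interval. Read lengths and arm use were compared as shares. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

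The comparisons, lists, thresholds and most alternatives were fixed before the data were examined. Of the alternatives, counting from the exact 5' end, TMM within a tissue and leaving out rRNA and tRNA fragments were added afterwards. Named miRNAs were the 10 with the largest change in each direction among those that passed a comparison (with none passing, the 5 with the smallest p), the 5 most abundant of each library, up to 4 of the highest members of each list and the whole let-7 Complex. Other names were chosen after their values were seen. Alternatives covered scaling, minimum reads, fold threshold, read lengths, mature arms, the test, the model terms and leaving out libraries.

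The steps were tested on simulated data. With 40 of 125 miRNAs changed by a log2 of 2, the edgeR step recovered 40 for the common sex difference, with 0 false calls, and 37 for heads against bodies, with 2 false calls. The simulated dispersion was 0.05, with the same mean profile in all 6 libraries. It was not matched to the spread of the real data, so these recoveries do not carry over to the real tests. On counts drawn with counting error alone, the counting intervals of the sex ratios covered the true ratio in 96.0% of cases in glands (43 miRNAs), 95.2% in heads (81) and 95.4% in bodies (93). The 2-fold rule recovered 100%, 100% and 99.8% of the 10 changed miRNAs. The planned count of reads at piRNA source loci was not run, since no genome sequence was at hand.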

Results

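Small RNAs of wild-type Oregon-R Drosophila melanogaster were sequenced from 3 tissues of each sex: salivary glands of larvae in instar 3, adult heads, and adult bodies without the head, the adults being 1 to 2 days old. Each of the 6 groups held 1 library. The files list every distinct read sequence with its read count, and the 6 libraries held 10900124 (male gland), 12852160 (female gland), 12295780 (male head), 12386083 (female head), 12052187 (male body) and 12866280 reads (female body). Known miRNA sequences took 2.35% and 3.65% of the reads of the male and the female gland, 9.91% and 17.3% of the heads, and 16.1% and 5.53% of the bodies. The comparisons asked how miRNA populations differ between the sexes within a tissue, and, beside that, how the 3 tissues differ.

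With 1 library per group there was no replicate check of a sex difference within a tissue and no p-value for it: such ratios compare 2 libraries, not the sexes. Their 95% intervals are exact Clopper-Pearson intervals for counting error only, since the reads are PCR products without molecular identifiers. Tests between tissues measured only the spread between these 6 libraries.

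The salivary glands were dominated by mir-8, a regulator of growth and of fat body signalling, which made up 33.6% of the miRNA reads in the male library and 39.3% in the female library. The other abundant miRNAs of the male gland were mir-263a, a protector of sensory organ cells from cell death, at 11.2%, mir-375 at 6.95%, mir-12 at 6.61% and mir-304 at 5.81%. The same miRNAs held 8.62%, 7.31%, 9.35% and 6.26% in the female gland. In heads mir-8 (15.6% in males, 11.9% in females) and the muscle miRNA mir-1 (11.2% and 8.76%) led, with the growth regulator bantam at 8.80% and 7.37% and mir-276a at 6.27% and 7.92%. Among the counted miRNAs, mir-277, a regulator of amino acid breakdown, came next in the male head, at 4.82%. In the female head it was mir-210, which acts in photoreceptors, at 5.37%. Bodies were led by mir-1 (27.2% and 29.7%), mir-8 (24.1% and 27.4%), bantam (12.9% and 10.5%) and mir-276a (4.83% and 4.72%). These were followed by mir-277 at 3.97% in males and by mir-2a, of a family that represses cell death genes, at 3.01% in females. The Clopper-Pearson intervals of these 30 shares reached at most 0.184 points from the share. The shares and ranks leave out the 5p arm shared by mir-276a and mir-276b. That arm had 60965 reads in the male head, against 55790 of mir-277. In the female body it had 33781, against 31988 of mir-276a and 20410 of mir-2a. The order given therefore holds only without it.

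The female body library stood apart in composition. Fragments of the 2S rRNA, which the library protocol removes, made up 9.35% of its reads, against 0.260% to 0.908% in the other 5 libraries, and 43.6% of its reads were 16 to 19 nt long, against 5.74% to 25.6%. A 5' fragment of tRNA-Lys held 12.4% and 10.4% of the reads in the male and the female gland, 2.73% and 2.60% in heads, and 0.876% and 0.829% in bodies. The Clopper-Pearson intervals of the shares of whole libraries reached at most 0.0271 points from the share.

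**Figure D1:**
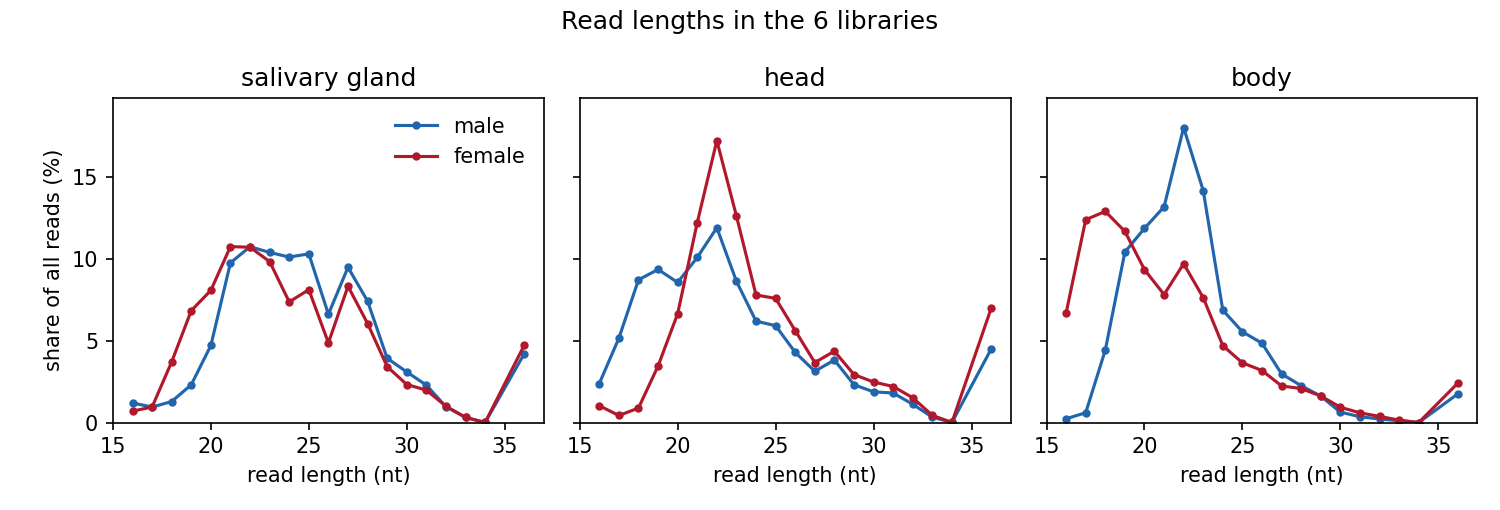
Share of all reads (%, vertical axis) against read length (nt, horizontal axis) in salivary glands, heads and bodies, with males in blue and females in red and each point 1 length in 1 library. The female body library held 43.6% of its reads at 16 to 19 nt and the male body library 15.7%.

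In salivary glands, mir-275 was 7.10-fold higher in the male than in the female library (interval 6.81 to 7.42, 13771 against 2475 reads). let-7, which is induced at the larval to pupal transition, was 6.31-fold higher in the female library (4.20 to 10.3, 197 against 24 reads). Higher in the female library were also mir-965, which lies within the gene kis, by 4.14-fold (3.39 to 5.12), and mir-279, which acts in carbon dioxide sensing neurons, by 3.68-fold (3.26 to 4.18). The neuronal list member mir-276a was 2.56-fold (2.39 to 2.74) and the X-linked mir-12 was 2.01-fold (1.98 to 2.05) higher in the female library. The 6 miRNAs named here were those at least 2-fold apart with an interval excluding 1, among 43 with 100 or more reads in at least 1 of the libraries. The 5p arm shared by mir-276a and mir-276b, left out of these counts, had 5589 reads in the female and 1864 in the male gland library. With mature arms counted apart 6 passed as well, that arm among the 5 higher in the female library.

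The median miRNA of the gland pair had a log2 male/female ratio of -0.46, so the ratios depended on scaling. With TMM computed between the 2 gland libraries alone, a choice made after the data were seen, the median was -0.01 and 6 miRNAs passed, 3 higher in each sex. Of these, 4 were shared with the main list: mir-276a and mir-12 lay under 2-fold, at log2 ratios of -0.91 and -0.57, while mir-278, a regulator of energy balance, and mir-252 passed at 1.38 and 1.17. Among the fixed lists, none of the 4 members of the mir-9b cluster passed. Their median log2 ratio was 0.13, at percentile 93.1 of 10000 sets matched on expression. The metabolism list had 1 of 7 members higher in the male library, mir-275, and the other 6 did not pass (percentile 88.0). None of 6 growth and cell death members (percentile 77.7), of 2 mirtrons (percentile 54.4), or of the single measured members of the muscle and Hox lists passed, and 1 of 4 neuronal members did, mir-276a (percentile 66.6).

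In heads, mir-190, which lies within the gene rhea, was 3.33-fold higher in the male library (2.93 to 3.78, 639 against 407 reads). Only 36.2% of its reads over the 6 libraries started exactly at the searched 5' end, and with those alone its log2 male/female ratio was 0.38 (159 against 234 reads), under 2-fold, which left no miRNA passing as higher in the male head. mir-981 and mir-980, both X-linked, the latter a memory suppressor, were higher in the female library, by 3.04-fold (2.52 to 3.71, 808 against 125 reads) and 2.01-fold (1.79 to 2.26, 1495 against 351 reads). These were the 3 that passed among 81 miRNAs with 100 or more reads, without the 5p arm shared by mir-276a and mir-276b. That arm had 60965 reads in the male and 57756 in the female head library. With mature arms counted apart 4 passed, 2 higher in each sex, that arm among those higher in the male library. Of 13 neuronal and sensory members 1 passed, mir-190, and the list median stood at percentile 46.8 of matched sets. None of 2 Hox members (percentile 92.8), 8 growth members (56.6), 7 metabolism members (38.0), 7 mirtrons (46.9), 4 mir-9b members (20.2), 3 let-7 Complex members (18.9) or 2 muscle members (28.2) passed. The count was not stable to scaling: 6 miRNAs passed with TMM within the head pair (1 higher in the male, 5 higher in the female library), 10 with DESeq2 size factors and 37 with scaling by all reads, all 37 higher in the female library.

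In bodies, the ovary miRNA mir-989, which acts in border cell migration, was 1021-fold higher in the female library (774 to 1411, 13603 against 46 reads). The testis cluster miRNAs went the other way: 15 of 15 measured members were higher in the male library, with a median log2 male/female ratio of 4.24. That median stood at percentile 98.6 of 10000 matched sets, which could hold testis members themselves. The central 95% of the sets' medians ran from 0.36 to 4.23. The list median was 4.24 also with the member lacking female reads set at its bound. mir-977 was at least 54.0-fold higher in the male library (566 reads against 0, set at a floor of 3 counts in that library). mir-976 was 43.6-fold higher (15.0 to 451, 380 against 2 reads), mir-978 was 42.1-fold higher (11.2 to 2500, 220 against 1) and mir-983 was 26.6-fold higher (13.1 to 78.8, 603 against 6). mir-303 had 149 against 1 reads (28.6-fold, 7.54 to 1697). When a read had to start exactly at the searched 5' end, 1 male and 0 female reads were left, too few to measure its ratio. mir-974 was 26.3-fold, mir-959 was 22.2-fold (7.55 to 230) and mir-984 was 18.9-fold higher (9.33 to 56.1). Outside that list, mir-997 was at least 16.1-fold higher in the male library (169 reads against 0) and the X-linked mir-985 was 26.0-fold higher (226 against 2).

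In all, 22 of 93 body miRNAs passed, 19 higher in the male and 3 in the female library. Of the 19, 15 were on the testis list and 11 were X-linked. Without that list 7 passed: mir-985, mir-997, mir-12 (2.36-fold) and mir-304 (2.73-fold) were higher in the male library, the last 2 named after their values were seen, and mir-989, mir-190 (3.37-fold, 2.57 to 4.42) and mir-275 (2.39-fold, 2.17 to 2.63) in the female library. With scaling by all reads, where the median moved from 0.08 to 1.98, the ratios of mir-190 and mir-275 turned to log2 0.15 and 0.64 and 89 miRNAs passed, 88 higher in the male and 1 in the female library. With reads starting exactly at the searched 5' end alone, mir-190 in bodies lay under 2-fold, at log2 -0.57. The 5p arm shared by mir-276a and mir-276b, left out of these counts, had 47144 reads in the male and 33781 in the female body library. With mature arms counted apart 23 passed, 19 higher in the male and 4 in the female library after scaling, that arm among the 4. The minimum of 100 reads asked more of the female library, which held 677399 miRNA reads against 1889582 in the male body library. With a minimum of 10 reads 36 passed, 28 higher in the male and 8 in the female library. The other ovary members lay below 100 reads: mir-318 had 71 reads in the female and 4 in the male library (55.5-fold, 23.2 to 234) and mir-994 had 69 and 3 (69.3-fold, 26.4 to 399). Of the 7 metabolism members 1 passed, mir-275, and the list median stood at percentile 97.1. The 4 members of the mir-9b cluster did not pass (percentile 6.15), nor did 8 growth members (20.9), 3 Hox members (77.9), 5 mirtrons (11.7), 2 muscle members (51.9) or 3 let-7 Complex members (40.8). Of 13 neuronal members 1 passed, mir-190 (percentile 44.4). The composition of the female body library given above, with 9.35% 2S rRNA, stood beside all of these ratios.

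**Figure D2:**
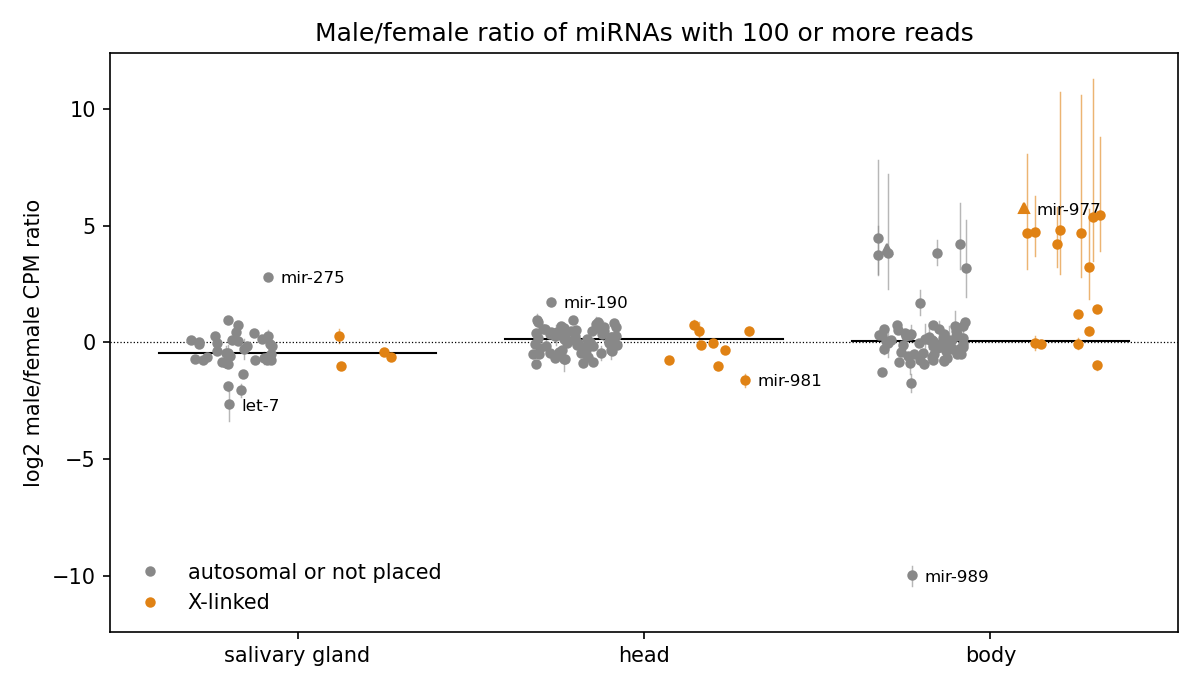
Log2 male/female CPM ratio (vertical axis) of every miRNA with 100 or more reads in at least 1 library of a tissue (horizontal axis), grey for autosomal or not placed and orange for X-linked, with vertical lines for 95% counting intervals, black bars for tissue medians and triangles for lower bounds against 0 reads. In bodies, mir-976 lies at 5.45 and mir-989 at -10.00.

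No miRNA passed the test of a sex difference common to the 3 tissues. The 5 smallest p-values were those of miRNAs with few or no reads outside the bodies. Of these, mir-974 of the testis list had a log2 male/female value of 5.06 ± 1.79 (SE), mir-985 of 4.58 ± 1.69 and mir-984 of 2.72 ± 1.34, and the ovary miRNA mir-318 of -4.48 ± 1.70. For mir-997, with 169 reads in the male body library and 0 in every other library, no fitted value is given. The edgeR quasi-likelihood test called 0 of 125 miRNAs, with 4 at an unadjusted p under 0.05 and a smallest Benjamini-Hochberg adjusted p of 0.768, and DESeq2 called 0, with 2 at an unadjusted p under 0.05. In camera tests with a preset correlation the testis list was higher in males (16 members, adjusted p = 1.16e-07; adjusted p = 0.745 with an estimated correlation). The ovary list was lower (3 members, adjusted p = 0.000361; adjusted p = 0.745 with an estimated correlation). None of the members of either list passed, over all miRNAs or adjusted over the list alone. The testis list as a whole was higher in the male library only in bodies, with 6002 against 108 reads. In heads it stood at 68.9 CPM in the male and 95.2 CPM in the female library, and in glands it had 1 and 2 reads. Its camera result therefore rested on 1 pair of libraries and does not show a difference common to the tissues. The other 10 lists had 0 members passing and camera adjusted p-values of 0.0540 or more. Without the head libraries 17 miRNAs were called, 14 higher and 3 lower in males. For testis members, with almost no gland reads, that fit compared little more than the male with the female body library. Without the gland libraries 1 was called, mir-989.

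X-linked genes are present in a single copy in males. In bodies, the median log2 male/female ratio of 16 X-linked miRNAs lay 3.75 above that of 75 autosomal miRNAs (counting interval 2.93 to 4.40), and the X-linked median stood at percentile 99.9 of matched sets. Of the 16, 11 passed as higher in the male library and 0 as higher in the female library. Without the testis list the difference was 0.26, over 8 X-linked miRNAs, at percentile 83.0, and it was 0.56 with each genomic cluster taken as 1 unit. In heads, 9 X-linked miRNAs lay -0.26 from 71 autosomal ones (-0.35 to -0.18), at percentile 12.0, mir-980 and mir-981 being the 2 that passed. In glands, 4 X-linked miRNAs lay -0.08 from 38 autosomal ones, at percentile 50.8, with a counting interval that includes 0 (-0.24 to 0.01). With each genomic cluster taken as 1 unit, only 2 X-linked units were left, and the difference was 0.13.

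The let-7 Complex, 3 cotranscribed miRNAs induced at the larval to pupal transition, stood furthest apart between the sexes in the glands, where let-7 was 6.31-fold higher in the female library. There mir-100 was 5.48-fold higher in the female library, but on 10 reads against 1 (1.11 to 340). mir-125 was 1.62-fold higher in the female library (46 against 22 reads), with an interval of 0.965 to 2.86 that includes 1. The sum of the 3 stood at 180.0 CPM in the male and 759 CPM in the female gland, against 20399 and 25855 CPM in heads and 19071 and 18365 CPM in bodies. In heads, let-7 was 1.24-fold and mir-125 was 1.42-fold higher in the female library, while mir-100 was 1.36-fold higher in the male library and turned to a log2 ratio of -0.63 with scaling by all reads. In bodies, let-7 was 1.08-fold higher in the male library. mir-100 and mir-125 were 1.19-fold and 1.13-fold higher in the female library, but at log2 male/female ratios of 0.0783 and 0.14 with scaling by total miRNA reads. So 2 of 9 pairs were past 2-fold, both in glands, and 1 pair was with TMM within the tissue, where the interval of mir-100 included 1. Over the 3 tissues the edgeR value of let-7 was -0.87 ± 0.57 (SE, adjusted p = 0.992). The genes lie together on chromosome 2L of the dm6 assembly, mir-100 at 18471434 to 18471533, let-7 at 18472034 to 18472111 and mir-125 at 18472315 to 18472424.

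**Figure D3:**
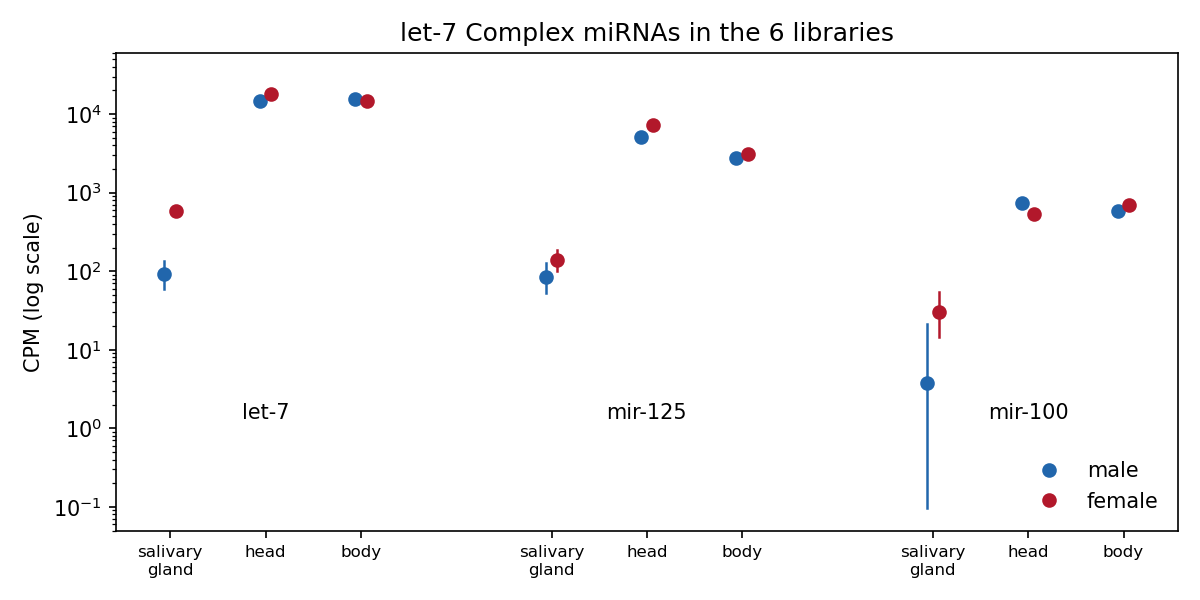
Scaled read counts (CPM, vertical log axis) of let-7, mir-100 and mir-125 in the 6 libraries, with blue for males, red for females and bars for 95% counting intervals. Gland values of let-7 are 91.9 CPM in the male and 591 CPM in the female library.

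Heads against bodies set the whole adult head, with its brain and eyes, against the trunk, with its gut and gonads. In heads, mir-285 rose by 10.05 ± 0.96 (SE) on the log2 scale (adjusted p = 2.12e-05), with 100816 reads against 79. The photoreceptor miRNA mir-210 rose by 7.13 ± 0.68, mir-193 by 8.20 ± 1.58, mir-315, an activator of Wingless signalling, by 6.08 ± 0.87 and mir-1000, which limits glutamate release, by 4.76 ± 0.59. mir-990 (5.72), mir-927 (4.70), mir-276b (4.51), mir-932 (4.33) and mir-987 (4.09) rose as well. Lower in heads were the ovary miRNA mir-989 (-11.22 ± 2.67), mir-958 (-9.39 ± 0.87), mir-956 (-9.23 ± 0.89), mir-314 (-8.67 ± 0.71) and mir-31b (-6.62 ± 0.93). The mirtron mir-1014 and mir-997 had 0 reads in heads and were at least 98.3-fold and at least 98.9-fold lower, the latter on the male body library alone (169 reads, against 0 in the female body). mir-iab-8 of the bithorax complex, which represses Hox genes, was lower (-7.65), as were mir-985 (-6.73) and the mirtron mir-1015 (-6.22).

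Of 13 neuronal and sensory miRNAs 9 were higher in heads and 4 did not pass, with 9 adjusted over the list alone. Its highest members were mir-210, mir-1000, mir-276b and the neural miRNA mir-124 (4.06 ± 0.58); by level, mir-34 rose by 2.51 ± 0.52, while mir-263a (0.71) and mir-276a (0.05) did not pass. The list's camera adjusted p was 0.000270, and its adjusted p was 0.806 with an estimated correlation. Of 4 Hox members 3 were lower, mir-10 (-2.29), mir-iab-4 (-5.62) and mir-iab-8, and mir-993 did not pass (-0.01). The muscle list split: mir-1 was lower in heads (-1.99 ± 0.62) and mir-133 higher (3.07 ± 0.57). Of 7 metabolism members 1 was lower, mir-33 (-1.81), and of 9 growth members 1 was higher, mir-13a (3.16). In the mir-310 cluster 1 of 4 was lower, mir-311 (-5.02), and 3 were adjusted over the list alone. In the ovary list 1 of 3 was lower, 2 adjusted over the list alone. Of 12 mirtrons 2 were lower, although the list's median was 0.90 and its mean -0.25. None passed among 3 let-7 Complex members, 4 mir-9b members, 2 mir-309 cluster members or 16 testis members, the last with a camera adjusted p of 0.0116 (lower in heads; adjusted p = 0.806 with an estimated correlation).

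The edgeR quasi-likelihood test called 49 of 125 miRNAs for heads against bodies (27 higher, 22 lower in heads), 2 libraries against 2 with sex as a covariate. With total miRNA scaling, which moved the median from -0.27 to 0.29, 35 were higher and 18 lower. Without the male head library mir-989, mir-985, mir-276b, mir-987 and mir-997 no longer passed, and without the female head library mir-989 did not pass either. The value of mir-989 rested on single libraries: it was log2 -12.36 without the male head, -6.86 without the female head, -13.25 without the male body and -3.67 without the female body library. With DESeq2 the adjusted p was 0.138 for mir-1015 and 0.143 for mir-997, with total miRNA scaling it was 0.0685 for mir-1015, and with no sex term it was 0.0722 for mir-997.

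Salivary glands against heads compared a larval secretory tissue with the whole adult head. In glands, mir-375 rose by 10.77 ± 0.84 (SE) on the log2 scale (adjusted p = 7.70e-06), with 51585 reads against 227. The X-linked cluster within the gene Gmap rose together, mir-12 by 6.85 ± 0.79, mir-283 by 6.66 ± 0.69 and mir-304 by 6.47 ± 0.75. mir-275 rose by 5.51 ± 1.04 and mir-263a by 3.43 ± 0.57. In the mir-309 cluster, which acts in clearing maternal mRNAs from the embryo, mir-286 (4.70) and mir-5 (3.70) rose, on 54 and 39 gland reads. The mirtron mir-1012 (3.33) and mir-306 (2.71) completed the named set. Several miRNAs of heads had 0 gland reads: mir-315 was at least 142-fold lower, mir-927 at least 48.3-fold, mir-990 at least 37.7-fold, mir-219 at least 24.5-fold, mir-1017 at least 22.4-fold, mir-1001 at least 16.3-fold and mir-955 at least 6.22-fold. Lower as well were mir-124 (-8.86 ± 0.73), mir-276b (-8.58 ± 0.85) and mir-285 (-8.33 ± 0.90).

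All 3 members of the let-7 Complex were lower in glands than in heads: let-7 (-5.86 ± 0.81), mir-125 (-5.79 ± 0.58) and mir-100 (-5.31 ± 0.90). Both muscle members were lower, mir-1 (-4.39) and mir-133 (-7.89). Of 13 neuronal members 11 were lower, 1 was higher, mir-263a, and mir-190 did not pass (-0.03). The list's camera adjusted p was 0.0303, and its adjusted p was 0.574 with an estimated correlation. Metabolism members went both ways: mir-8 (1.97), mir-33 (2.13), mir-275 and mir-305 (1.89) were higher, mir-277 (-3.30) and mir-14 (-1.34) were lower, and mir-278 did not pass (-0.09). In the mir-9b cluster, mir-306 and mir-9b (1.99) were higher and mir-79 (0.75) and mir-9c (0.61) did not pass. Its camera adjusted p and that of the mir-309 cluster (2 of 2 higher) were both 0.0303, and both adjusted p-values were 0.574 with an estimated correlation. Of 9 growth members mir-11 (2.28) was higher and 2 were lower, of 4 Hox members mir-993 (-8.28) was lower, and of 12 mirtrons mir-1012 was higher and mir-1010 (-7.25) lower. None of 16 testis, 3 ovary or 4 mir-310 members passed. For the testis, growth and mirtron lists the medians (-4.13, -0.07 and -1.37) were negative while camera ranked them up, without passing.

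The edgeR quasi-likelihood test called 63 of 125 miRNAs for glands against heads (20 higher, 43 lower in glands), around a median of -2.26, and DESeq2, with a median of -0.54, called 28 higher and 40 lower. Without the male head library the adjusted p of mir-275 was 0.0803 and that of mir-306 was 0.0529; without the male gland library it was 0.0745 for mir-286, 0.141 for mir-5 and 0.0751 for mir-955, and without the female gland library 0.194 for mir-5 and 0.109 for mir-955. With DESeq2 the adjusted p of mir-955 was 0.0619, and with total miRNA scaling that of mir-5 was 0.0907. The value of mir-275 was log2 3.07 without the male gland library.

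Glands against bodies compared the larval tissue with the adult trunk. In glands, mir-283 rose by 5.54 ± 0.66 (SE) on the log2 scale (adjusted p = 7.98e-05), mir-304 by 3.67 ± 0.67, mir-12 by 3.57 ± 0.70 and mir-375 by 5.37 ± 0.67. mir-275 rose by 4.95 ± 1.04, mir-263a by 4.14 ± 0.59, mir-286 by 4.83, mir-1012 by 4.40, mir-998 by 4.10 and mir-995 by 3.70. mir-31b, with 0 gland reads and 2532 body reads, was at least 205-fold lower. mir-958 (-11.17 ± 1.05) and mir-956 (-10.54 ± 1.06), each on 1 gland read, and mir-314 (-9.96 ± 0.79), on 5 gland reads, were lower too. Of the testis miRNAs, mir-983 was at least 49.3-fold, mir-964 at least 37.2-fold, mir-984 at least 35.2-fold and mir-963 at least 29.5-fold lower. These bounds rested on the male body library, which held 603, 451, 429 and 360 reads of the 4 against 6, 9, 6 and 5 in the female body. mir-iab-8 was at least 15.3-fold and mir-1014 at least 13.6-fold lower.

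All 4 Hox members were lower in glands than in bodies. Of these, mir-10 stood at -3.43 and mir-993 at -8.29, the latter on 1 gland read. For mir-iab-4, with 0 gland reads against 94 and 32 in the male and female body, no fitted value is given. All 3 let-7 Complex members (let-7 at -5.81, mir-100 at -5.29, mir-125 at -4.75) and both muscle members (mir-1 at -6.38, mir-133 at -4.82) were lower as well. Of 16 testis members 8 were lower, among them mir-960 (-6.65) and mir-962 (-6.10), and 8 did not pass, with 12 adjusted over the list alone. Of 13 neuronal members 8 were lower and 1 higher, mir-263a. Of 7 metabolism members mir-275 and mir-305 (2.05) were higher and mir-277 (-3.22) lower. The mir-309 cluster had 2 of 2 members higher, mir-286 and mir-5 (3.17), and the mir-9b cluster 1 of 4, mir-306 (2.44). In the mir-310 cluster mir-312 was lower, with 0 gland reads against 80 and 31 in the male and female body. Of 9 growth members mir-11 (1.72) was higher and mir-13a (-3.13) lower. Of 12 mirtrons mir-1012 was higher and mir-1010 (-5.79) and mir-1014 lower. None of 3 ovary members passed. No list had a camera adjusted p under 0.05. For the growth and mirtron lists the medians (-0.09 and -1.05) were negative while camera ranked them up.

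The edgeR quasi-likelihood test called 70 of 125 miRNAs for glands against bodies (16 higher, 54 lower in glands), around a median of -3.43, and DESeq2, with a median of -2.65, called 24 higher and 46 lower. Without the male gland library mir-286, mir-963 and mir-984 no longer passed, nor did mir-1014 without the female gland library. Without the male body library mir-964 no longer passed either. It was then left with 9 reads in the female body against 0 in both glands. With DESeq2 the adjusted p of mir-1014 was 0.0780. The value of mir-275 was log2 2.59 without the male gland library.

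Reads of 23 to 29 nt, the size range of piRNAs, were not most frequent in the bodies, which hold the gonads. Of the 18 to 30 nt reads they made up 64.6% in the male and 53.1% in the female gland, 40.4% and 50.9% in heads, and 39.5% and 32.4% in bodies, each with a Clopper-Pearson interval narrower than the last digit given. Female minus male differences were -11.5 points in glands, 10.5 in heads and -7.14 in bodies, far beyond counting error at these depths. The share of 18 to 20 nt reads went the other way in each tissue. It was 9.22% in the male and 20.6% in the female gland, 31.4% and 12.6% in heads, and 27.6% and 43.8% in bodies. The differences therefore cannot be told apart from unequal shares of short reads between single libraries. The body difference was -2.35 for 24 to 29 nt reads and -2.90 over distinct sequences. Reads starting with T, the usual first base of piRNAs, made up 27.0% and 27.3% of the 23 to 29 nt reads in the male and female gland, 33.1% and 34.4% in heads and 32.5% and 33.0% in bodies. Among all 18 to 30 nt reads, miRNA reads included, they made up 28.5% and 27.9% in glands, 33.6% and 38.0% in heads and 33.2% and 33.2% in bodies. The 23 to 29 nt reads did not exceed that background in any library. The background holds those reads themselves and the reads of 22 nt, of which 1208674 of 2170148 started with T in the male body. The comparison therefore cannot show or deny a first-base bias of piRNAs.

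No hairpin passed the rule set for a tissue difference in the use of its arms. Of 9 hairpins with both arms searched, 8 had 100 or more reads in each library, and 0 differed between tissues by more than 20 points in both sexes. mir-281 came nearest, for heads against bodies, with 58.4% (Clopper-Pearson interval 53.9 to 62.9) and 49.0% (45.7 to 52.2) of reads from the 5p arm in the male and female head, 25.2% and 29.2% in bodies, and 56.9% (46.7 to 66.6) and 46.4% (38.9 to 54.0) in glands. mir-10 stood at 60.5% (53.4 to 67.3) and 56.9% (51.9 to 61.8) in glands, 42.5% and 37.9% in heads and 52.0% and 59.8% in bodies.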

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

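All tests of explanations in this part were chosen only after the results they measure had been seen.

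The male/female ratio of mir-275 had opposite directions in glands and bodies, at log2 2.83 and -1.26, a difference of 4.09 that was not tested. The ratio of mir-190 likewise differed by 3.49 between heads (1.73) and bodies (-1.75), and that of mir-12 by 2.25 between bodies (1.24) and glands (-1.01, or -0.57 with TMM within the gland pair), both untested. With reads from the exact 5' end alone, mir-190 stood at 0.38 in heads and -0.57 in bodies, under 2-fold in both. A sequence of the Su(Ste) piRNAs of the testis, outside the miRNA counts, had 433 reads in the male body library (Poisson interval 393 to 476; 35.9 RPM), 1 in the female head library and 0 in the other 4, where 3 counts would be at most 0.275 RPM.

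Higher mir-275 in the male gland library was weighed against library artifacts. It lay 4.12 residual SD above the trend of log2 ratio on GC content over the other 42 miRNAs, which argues against GC bias as the whole cause. Its reads other than the commonest sequence were 3.31-fold higher in the male library (3.08 to 3.57), which argues against amplification of a single sequence as the whole cause, although that sequence held 81.2% of its reads there and 59.7% in the female library. mir-305, in the same cluster with its start 177 bp from that of mir-275, had a ratio of 0.969 (0.939 to 1.00). That argues against higher transcription of the whole cluster as the whole cause. A smaller rise of the cluster stays open, since this ratio lay above the gland median (log2 -0.46) and mature reads do not measure transcription. A difference in processing of mir-275, between the sexes or between these 2 dissections, may remain and was not tested.

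Lower let-7 in the male gland library was weighed against carry-over and scaling. Had the 166 excess let-7 reads of the female gland come from whole male bodies, the source that came closest, mir-1 would need 2847 reads where 1615 were found, a share of 0.567 (0.476 to 0.696). That argues against whole adult heads or bodies as the only source, though the bound was set after this value was seen, a first bound of 0.5 would have left the question open, and RNA of other larval or single adult tissues was not tested. Over 5 scalings the highest log2 ratio was -2.15, which argues against scaling. A later stage of the female glands and a sex difference cannot be told apart with 1 library each: mir-100 and mir-125 together stood at 0.719 of the median miRNA's ratio (0.422 to 1.19), an interval that leaves the question open.

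Testis-cluster miRNAs had reads in heads, with the autosomal mir-959 to mir-964 at 50.8 CPM in the male and 82.2 CPM in the female library. Carry-over of male body RNA would bring the X-linked testis miRNAs in proportion, but the autosomal set was over-represented against them by an odds ratio of 5.68 (3.99 to 8.29) in the female head, which argues against that source as the whole cause there, while in the male head it was 2.45 (1.53 to 4.05), an interval reaching below the bound of 2, so that carry-over and expression cannot be told apart there (4.38 over both heads). The female body library held the autosomal set too, at 158 CPM, but carry-over of whole female bodies would bring the ovary miRNA mir-989, of which at most a share of 0.000271 of the reads needed was found (0 to 0.000646), which argues against that source as the whole cause. The female head library held the autosomal set at 1.62 times the male level (1.23 to 2.14). For the female head these values are consistent with expression of that cluster there, as a hypothesis, but carry-over of trunk tissue other than gonads was not tested for either head.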

How the results depend on the processing

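The alternatives counting from the exact 5' end, with TMM within a tissue, and without rRNA and tRNA fragments were chosen only after the results were seen. The 3 tissue comparisons kept their total counts within 1.5 times under every alternative run, and arm use stayed at 0. The miRNAs called were not all the same. DESeq2 shared 45 of the 49 calls for heads against bodies, 60 of 63 for glands against heads and 60 of 70 for glands against bodies. Most refits without a library shared fewer of the main calls than that. The common sex difference stayed at 0 calls except without a tissue, where the calls ran from 0 to 17. The real count was 0, which all 10 of the 10 splits of the 6 libraries into 3 and 3 reach whatever the data, so that number decides nothing, and 10 splits are too few for a share under 0.05. The highest other split gave 22. The 2 splits with 22 calls set both gland libraries with a body library against the rest. With the tissue term kept, such a split compares only the male with the female body library. The spread then comes from the gland pair and the head pair.

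The cause of the following shifts was not tested, except that lower thresholds and minimums admit more miRNAs by construction. Sex differences in glands, 6 in the report, numbered 10 with a minimum of 10 reads and with no minimum, 22 at 1.5-fold and 3 at 4-fold. In heads, 3 in the report, there were 6 with total miRNA scaling, with 21 to 24 nt reads and with TMM within the tissue, 10 with DESeq2 size factors, 37 with all reads as scaling, 9, 11 and 1 with a minimum of 10, none and 1000 reads, 24 at 1.5-fold, 0 at 4-fold and 5 with the exact 5' end. In bodies, 22 in the report, there were 89 with all reads as scaling, 36, 37 and 5 with a minimum of 10, none and 1000 reads and 37 at 1.5-fold. The let-7 Complex had 1 pair past 2-fold with total miRNA scaling, 21 to 24 nt reads, the exact 5' end or TMM within the tissue, and 7 with all reads as scaling.

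The X minus autosomal difference was 0.0903 with 10 reads and 0.13 with clusters as units in glands, and -0.13 with 10 and -0.47 with 1000 reads in heads. In bodies it was 0.94 with 1000 reads, 0.26 without the testis list, 2.87 by means and 0.56 with clusters as units. The female minus male share of 23 to 29 nt reads kept its direction. For 24 to 29 nt, distinct sequences, without miRNA reads, without the 10 most abundant sequences and without miRNA, rRNA and tRNA fragments, it was -10.9, -9.82, -11.8, -10.1 and -11.3 in glands, 6.26, 10.8, 13.5, 8.62 and 13.8 in heads, and -2.35, -2.90, -7.57, -6.26 and -7.46 in bodies.

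Of 933 settings of named miRNAs, 833 kept their direction and side of the threshold, 25 lost the call, 5 gained it, 62 moved beyond counting error and 8 changed sign. For mir-303 in bodies with the exact 5' end the sign (log2 -0.24) came from 0.5 reads added to 1 male and 0 female reads, so its direction was not measured there. The others were, in log2 male/female, with all reads as scaling mir-190 (0.15), mir-275 (0.64), mir-100 (1.65) and mir-125 (1.72) in bodies and mir-100 in heads (-0.63). With total miRNA scaling mir-100 (0.0783) and mir-125 (0.14) turned in bodies. Of 60 tissue values of named miRNAs, 37 moved by over 1.5 times in at least 1 refit without a library, in 91 of 227 such refits. The count at piRNA source loci and its 3 alternatives were not run. In glands 43 miRNAs reached 100 reads, against 81 in heads and 93 in bodies; whether depth or expression set this was not tested.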

Other observations

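The values below were picked only after they had been seen, and no explanation of them was tested.

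The X-linked genes mir-283, mir-304 and mir-12 lie within Gmap, at 15507956 to 15509546 on dm6, and differed in their sex ratio in bodies. There mir-12 and mir-304 were 2.36-fold (2.26 to 2.45) and 2.73-fold (2.60 to 2.87) higher in the male library, while mir-283 had a male/female ratio of 0.504 (0.442 to 0.577). In glands all 3 were lower in the male library, at log2 -1.01, -0.62 and -0.39 for mir-12, mir-304 and mir-283, around a median of -0.46, but mir-283 stood at 0.05 with TMM within the tissue.

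The ovary miRNA mir-989 was also seen outside bodies, with 30 reads in the female and 14 in the male gland library, against 7 and 3 in heads. The mir-310 cluster was nearly absent outside bodies, at 139 CPM in the male and 97.2 CPM in the female body library, against 8.71 and 4.79 CPM in heads, 3.83 CPM in the male gland (1 read) and 0 reads in the female gland.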
